A study of Mus musculus with 4 samples.

How the data were processed

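Sorted vessel progenitor cells of C57BL/6 mice were measured in 4 droplet-based single-cell RNA libraries, 1 each for the populations P1 and P2 of fat and of lung. Libraries were made with a 10x Genomics Chromium Next GEM kit for the 3' ends of transcripts, and the submitters' processing notes name Cell Ranger 3.1.0 and the genome build mm10. The deposited matrices hold counts, that is UMIs per gene and cell barcode, with no normalization, for barcodes already called as cells. Each matrix had 31053 gene entries, and the 35 symbols shared by several gene IDs were summed, which gave 31017 symbols. The release of the gene annotation, the sex and the number of animals are not stated in the sources used here. Coordinates of the sort gate genes came from GENCODE vM21 on GRCm38, matched by gene ID.

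Depth differed between libraries. The libraries held 3783 barcodes (labelled fat P1), 9025 (fat P2), 1305 (labelled lung P1) and 2860 (lung P2), with 8866500, 44711105, 1510443 and 5348607 UMIs. The lowest barcode total was 282 UMIs in the library labelled lung P1 and 500 in each of the others. Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes were kept. More than 10% mitochondrial UMIs were found in 1645, 672, 16 and 847 barcodes, in the same order. The barcodes with the highest Scrublet scores were then removed at a rate of 0.8% per 1000 barcodes, which took out 30, 499, 3 and 16. Scrublet's automatic threshold marked 1 of 7898 fat P2 barcodes and was kept only as an alternative. This left 1918, 7399, 649 and 1420 cells with 6338224, 39045491, 1110700 and 3818577 UMIs and median UMIs per cell of 2949.5, 5066, 1560 and 2124.5. A gene with 0 counts in a library can stand at up to 3 counts, which is 0.473, 0.0768, 2.70 and 0.786 CPM (UMIs of a gene scaled to the library sum).

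Clusters were made within each library from 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. A cluster took the name of the marker list with the highest share of members at 100 CPM or more, with at least 3 members there. It stayed unnamed when its UMIs were low or when its 10 leading genes held more markers of another list than of its own. This naming rule, a minimum of 50 CPM for leading genes and the summing of shared symbols were chosen after the counts had been seen. Shares of cells have exact Clopper-Pearson 95% intervals. Shares of cells with a gene were counted after each cell was thinned to 2000 UMIs, with smaller cells left out.

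For each comparison UMIs were summed per library, scaled to CPM and expressed as log2 ratios after adding 10 CPM. "At least 4-fold" refers to this ratio, for genes at 50 CPM or more in 1 of the 2 libraries. The population comparisons used all kept cells, and the tissue comparisons used endothelial-like cells for P1 (550 and 1643) and fibroblast-like cells for P2 (820 and 7026). CPM values have exact Poisson 95% intervals. Both kinds of interval cover counting error only. With 1 library per group no test was run and no standard error was computed, and counts of genes describe these libraries alone. A fit that treats the tissues as replicates of a population was not run, because fat and lung are different conditions. Where a gene had 0 counts in 1 library, the fold is given as a lower bound against 3 counts. List medians are then given also with such genes at the log2 of that bound, in which no CPM are added, while the other members keep the added 10 CPM.

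Before the data were examined, 28 gene lists and 15 marker lists were written, together with the filters, the comparisons, the size rule and the alternatives. A list member was measured at 20 CPM or more in 1 of the 2 libraries. The median log2 ratio of a list was placed among 10000 random lists matched on expression in 20 bins, and the range given with it holds 95% of their medians. This placement also describes these libraries and is not a test. The use of 4-fold for list members was added after the counts had been seen. Named genes are the 10 highest and 10 lowest of each comparison (without mitochondrial, ribosomal and unnamed transcripts), the sort gate genes, up to 4 members of each list with the largest ratios, and the 10 leading genes of a cluster. Any other gene named was chosen after its values were seen. Not every cluster, and not every gene that this rule names, is reported here.

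Counts with known changes were simulated with counting error as the only noise, which leaves out differences between animals or preparations. The 4-fold rule then called 0% of genes changed 1-, 2- or 3-fold and 100% of genes changed 8- or 16-fold, in all 4 comparisons. Of 100 unchanged lists per comparison 1, 6, 1 and 4 fell outside the random range, and all 20 lists raised 2-fold fell above it. Most genes were unchanged in the simulation, whereas in the data random lists for the endothelial markers in fat ranged from -1.71 to 1.203 log2. A list raised 2-fold can therefore lie inside its random range in the data. Alternatives were a pseudocount of 1 CPM, edgeR TMM and median-of-ratios scaling, a mean over cells, a 10 CPM minimum, all barcodes, no doublet removal, a 2-fold threshold, other sets of cells, other cluster settings and other thinning. Exchanging the P1 libraries between the tissues and naming clusters by their markers alone were added after the counts had been seen. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.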

Results

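Vessel progenitor cells were sorted from the fat and lung of C57BL/6 mice into populations P1 and P2 and profiled by single-cell RNA sequencing, with 1 library per tissue and population. Both gates excluded CD45, a leukocyte protein, and Ter119, an erythroid antigen, and required Tie2, the angiopoietin receptor. P1 was CD31 positive, PDGFRa negative, CD105 high and Sca1 low, and P2 was CD31 negative, PDGFRa positive, CD105 low and Sca1 high. The kept cells numbered 1918 (labelled fat P1), 7399 (fat P2), 649 (labelled lung P1) and 1420 (lung P2), with 6338224, 39045491, 1110700 and 3818577 UMIs. There were no replicates, so each difference below is a description of single libraries. Tissue markers in the P1 libraries contradicted their labels. Fabp4, a fatty acid binding protein of adipose vessels, stood at 12392 CPM in the library labelled lung P1 and 96.6 CPM in the library labelled fat P1. Foxf1, a transcription factor of lung vessels and mesenchyme, stood at 3.60 and 714 CPM, and Sftpc, the surfactant protein of lung epithelium, at 0 and 757 CPM. Fat and lung in every P1 value below are therefore labels, and each direction between tissues is drawn as labelled.

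The first question was whether the RNA of the sort gate genes followed the gates. Pecam1 (CD31) and Eng (CD105) were higher in P1 than in P2 in both tissues, and Pdgfra was higher in P2. Pecam1 (ENSMUSG00000020717, mm10 chromosome 11, 106654217 to 106750628) stood at 1752 CPM (1720 to 1785) in the library labelled fat P1, 2.66 in fat P2, 1217 in the library labelled lung P1 and 89.6 in lung P2. Eng (ENSMUSG00000026814, chromosome 2, 32646595 to 32682669) stood at 1295, 46.8, 972 and 99.5 CPM in the same order. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215) stood at 9.47, 443, 14.4 and 1748 CPM. Tek (Tie2, ENSMUSG00000006386, chromosome 4, 94739289 to 94874976) stood at 690.3, 165, 229.6 and 41.4 CPM. Ly6a, which encodes Sca1 (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), stood at 2412 CPM in the library labelled fat P1 and 1942 in fat P2, and at 1754 in the library labelled lung P1 and 208 (194 to 223) in lung P2. In lung, its RNA was thus not lower in the population gated as Sca1 low, with a log2 ratio P1 over P2 of 3.02 as labelled and 3.47 with the P1 libraries exchanged. In fat the direction was not settled: the log2 ratio of Ly6a was 0.31 as labelled, -0.18 with TMM scaling and -0.15 with the P1 libraries exchanged. Ptprc (CD45, ENSMUSG00000026395, chromosome 1, 138062861 to 138175708) stood at 4.58, 1.46, 18.9 and 4.45 CPM.

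At 2000 UMIs per cell, Pecam1 was seen in 93.1% (91.7 to 94.3) of cells labelled fat P1, 0.298% of fat P2, 90.7% (85.1 to 94.7) of cells labelled lung P1 and 2.62% of lung P2, and without thinning in 95.9%, 0.568%, 84.7% and 2.32%. Thinning left out 453, 680, 488 and 656 cells. Among fibroblast-like cells, which should lack Pecam1, it was seen in 0.169% in fat P2 and in 0 of 499 cells in lung P2 (upper limit 0.737%), at unthinned median depths of 5126.5 and 2338 UMIs. Pdgfra was seen in 0.41% of cells labelled fat P1, 53.2% of fat P2, 3.11% of cells labelled lung P1 and 81.8% of lung P2 when thinned, and in 0.521%, 76.3%, 2.47% and 84.5% unthinned. Endothelial-like cells, which should lack Pdgfra, carried it in 0.0832% of cells labelled fat P1 and 3.88% of cells labelled lung P1, at median depths of 2804 and 1549.5 UMIs. Tek was seen in 64.0% of cells labelled fat P1, 27.0% of fat P2, 31.1% of cells labelled lung P1 and 2.88% of lung P2 (71.6%, 47.8%, 31.1% and 3.45% unthinned). In fibroblast-like cells Tek was seen in 27.5% in fat P2 and 1.80% (0.828 to 3.40) in lung P2. Ly6a was seen in 90.03%, 84.7%, 96.3% and 8.25% of cells thinned and in 89.99%, 87.8%, 91.8% and 7.54% unthinned. Eng was seen in 87.4%, 8.08%, 87.6% and 11.3% thinned, and in 91.6%, 18.2%, 80.0% and 11.7% unthinned. Col1a1, a fibroblast collagen gene, was seen in 0.0832% of endothelial-like cells labelled fat P1 and in 30.2% of those labelled lung P1.

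**Figure D1:**
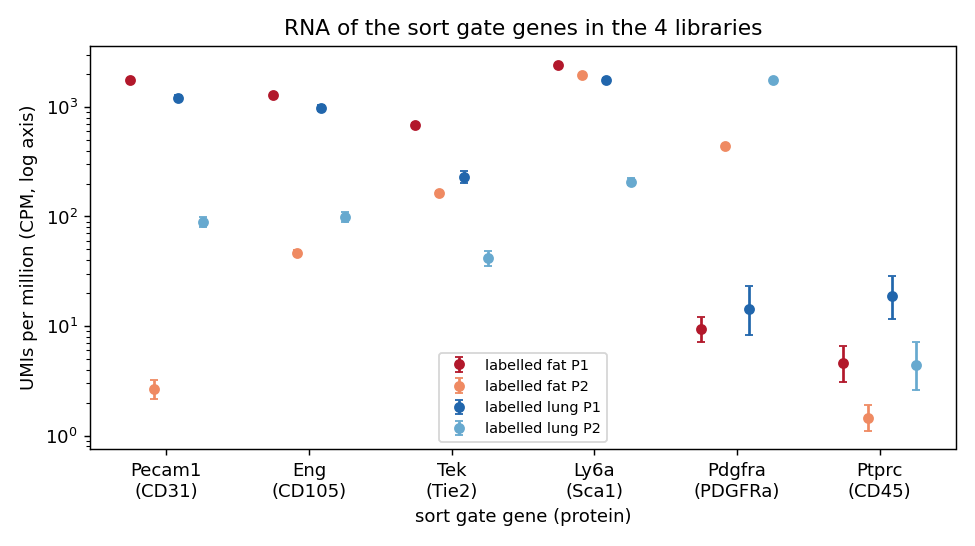
CPM (log axis) of the 6 sort gate genes in each of the 4 libraries, as labelled, over all kept cells. Points are library sums and bars their exact Poisson 95% intervals, which cover counting error only. Pecam1, Eng and Tek are higher in each P1 library and Pdgfra in each P2 library, while Ly6a stands at 2412 and 1942 CPM in the fat libraries and at 1754 and 208 CPM in the lung libraries.

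The composition of each sorted library was described next. Endothelial-like clusters held 85.7% (84.0 to 87.2) of the 1918 cells labelled fat P1 and 84.7% (81.7 to 87.4) of the 649 cells labelled lung P1. Barcodes of the library labelled lung P1 varied little more than random draws from its summed counts (variance 1.06 and 0.996 times the binomial expectation), and of those with enough UMIs to thin to 2000, 39.8% then held at least 3 UMIs each of endothelial and fibroblast markers. Values per cell for that library are therefore values of barcodes, which were not shown to be single cells. Fibroblast-like clusters held 94.96% (94.4 to 95.4) of the 7399 fat P2 cells and 57.7% (55.1 to 60.3) of the 1420 lung P2 cells. Lung P2 also held mural (5.07%), endothelial-like (1.83%) and epithelial (1.48%) clusters. A further 33.9% of its cells were in 2 unnamed clusters, whose leading genes included the mesothelial gene Upk1b in 1 and the lymphocyte gene Gzma in the other. Both matched fibroblasts best, with 9 and 8 of 12 markers at 100 CPM or more. Upk1b stood at 303 against 121 CPM in the other cells, and Gzma at 50.8 CPM against 0 counts. Both clusters were left out of the tissue comparison of P2. The library labelled fat P1 had an epithelial cluster of 39 cells (2.03%) led by Ager and Aqp5, genes of the alveolar epithelium. The remaining unnamed cells made up 12.3%, 5.04% and 15.3% of the libraries labelled fat P1, fat P2 and labelled lung P1. These shares moved with every alternative cluster setting tried: with resolution 0.5 the endothelial-like share was 38.6% in the library labelled fat P1 and 0% in the one labelled lung P1, and the fibroblast-like share of lung P2 was 91.8%. No cluster took the name of lymphatic endothelium, mesothelium, Schwann cells, muscle, adipocytes or any blood cell.

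Within the library labelled fat P1, the largest cluster (432 cells) was led by Fibin, Ednrb, Tbx2, Apln and Car4, genes of the lung capillary cells known as aerocytes. Other endothelial-like clusters were led by interferon-induced genes (Ifit1, Isg15 and Igtp, 162 cells), by Vwf, Slc6a2 and Vcam1 (43 cells) and by the arterial gap junction gene Gja5 (40 cells). An unnamed cluster of 148 cells combined Ccl21a and Mmrn1, genes of lymphatic vessels, with Gzma and Nkg7, genes of cytotoxic lymphocytes, and another of 88 cells was led by the immunoglobulin gene Igkc and Fabp4. In fat P2, 681 cells were led by Pi16, Dpp4, Il33 and Sema3c, markers of interstitial adipose progenitors, and 447 cells by F3, Clec11a, Fmo2 and Mgp, markers of stroma that regulates adipogenesis. The other fat P2 cells also carried the genes of the 681 cells, with Pi16 at 7484 against 4047 CPM and Dpp4 at 956 against 538 CPM. Further fat P2 clusters were led by Ifit1, Rsad2 and Cxcl10 (459 cells), by Col4a1, Nrep and Aoc3 (768 cells), by Cxcl13 (1423 cells) and by Dmkn, Sbsn and Dact2 (468 cells). Small unnamed fat P2 clusters were led by endothelial genes (17 cells; Fabp4 and Aqp1), mural genes (22 cells; Acta2 and Myh11), and genes of muscle satellite cells (34 cells; Pax7 and Myf5). Another was led by milk or mammary genes (80 cells; Csn3 and Lalba). Lung P2 held fibroblast-like clusters led by Scara5, Dcn, Lum and Ccl11 together with the B cell genes Igkc, Ighm, Iglc1 and Cd79a (76 cells), by Adh7 and Hmcn2 (84 cells), by Hhip, Aspn and Actg2 (22 cells) and by Mt2, Mmp3 and Gdf10 (210 cells). Its mural cluster (72 cells) was led by Postn, Cox4i2, Notch3 and Myh11, and its endothelial-like cluster (26 cells) by Ptprb, Vwf and Hpgd. The clusters of the library labelled lung P1 were led by scattered genes, apart from one of 17 cells led by Car3.

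The comparison of P1 with P2 in fat asked how the CD31-positive population differed in RNA from the PDGFRa-positive one. The library labelled fat P1 carried the genes of blood vessel endothelium and fat P2 those of matrix-producing fibroblasts and adipose progenitors. All 12 endothelial markers were at least 4-fold higher in P1 (median log2 5.92, random lists -1.71 to 1.203), and all 12 fibroblast markers were at least 4-fold higher in P2 (median log2 -7.34, or -7.54 with 0-count genes at their bounds without added CPM, random lists -1.75 to 1.24). Cldn5, a tight junction gene, stood at 3011 CPM (2968 to 3054) against 1.08 CPM (0.775 to 1.45), and the vascular adhesion genes Cdh5 and Icam2 at 2095 against 2.05 and 1179 against 0.512 CPM. Ptprb, Egfl7, Adgrf5, Pecam1, Cd93, Ctla2a and Cd36 completed the 10 highest ratios, for example Egfl7 at 2223 against 2.18 and Cd36, a fatty acid transporter, at 2118 against 10.1 CPM. Dcn, a matrix proteoglycan, stood at 13681 CPM (13644 to 13718) against 2.84 CPM (1.68 to 4.49) in P2 against P1, followed by Pi16 (4280.3 against 0.947 CPM), the collagens Col1a2 (6519.6 against 10.1), Col3a1 (8095 against 17.8) and Col1a1 (5511 against 10.1), and Igfbp5, Dpt, Clec3b and Fn1. Of 4726 genes, 588 were at least 4-fold higher in P1 and 477 in P2. TMM scaling shifted the median ratio of all genes by -0.57 log2, and the counts became 453 and 634, so that P1 held 41.7% of the calls in place of 55.2%.

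By vessel type, 6 of 7 measured capillary genes were at least 4-fold higher in the library labelled fat P1 (median log2 6.26), among them Car4 (957 against 0.589 CPM), Aqp1 (1389 against 5.97) and Gpihbp1 (919 against 2.15), which anchors lipoprotein lipase. The gene lists of lung capillaries were also higher there. All 8 general capillary genes (median log2 6.20) and 8 of 9 aerocyte genes (median log2 4.08) passed 4-fold, with Hpgd at 2501 against 17.6, Emp2 at 2029.6 against 38.2 and Ednrb at 609.6 against 0.333 CPM. Arterial genes were at least 4-fold higher in P1 for 6 of 8 members and in P2 for 1 (median log2 4.33), such as Efnb2 (830.2 against 15.5 CPM) and the Notch ligand Dll4 (227 against 0.154 CPM). Venous genes were at least 4-fold higher in P1 for 3 of 7 (Vwf at 261 against 0.666 CPM) and in P2 for 1, Ackr1 (median log2 1.27, random lists -1.08 to 1.14). Angiogenic receptors passed 4-fold in P1 for 9 of 13 and in P2 for 3 (median log2 3.29), with the VEGF receptors Flt1 at 915 against 2.07 and Kdr at 1290.4 against 13.7 CPM. Notch pathway genes passed it in P1 for 7 of 10 and in P2 for 1 (median log2 2.58), including Hey1 (241 against 3.02 CPM) and Notch4 (134 against 0.461 CPM). Antigen presentation genes passed it in P1 for 5 of 8 (median log2 2.72), such as H2-Ab1 at 238 against 5.74 CPM. All 3 measured lymphatic markers passed it in P1 (median log2 3.29), with Lyve1 at 693 CPM (673 to 714) against 0.0256 CPM (0.000648 to 0.143), the latter from 1 count. Epithelial markers passed it in P1 for 3 of 7 (median log2 1.84, random lists -1.48 to 1.26), with Sftpc at 757 against 0.154 and Ager at 468 against 0.282 CPM. Ager stood at 11405 CPM in the epithelial cluster of 39 cells and at 14.6 CPM in the other cells labelled fat P1. The epithelial median was 1.24 with endothelial-like against fibroblast-like cells, 0.93 with means over cells and 3.19 with all barcodes.

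In fat P2, interstitial matrix genes were at least 4-fold higher for 14 of 15 (median log2 -5.82) and basement membrane genes for 8 of 11 (median log2 -2.75), such as Lamb1 (371 against 4.1 CPM in P2 against P1) and Nid1 (1592 against 142 CPM). Interstitial adipose progenitor genes passed 4-fold for 7 of 10 (median log2 -2.76), among them Pi16, Cd55 (435 against 6.78 CPM) and Wnt2 (180.2 against 1.26 CPM). Genes of adipogenesis-regulatory stroma passed it in P2 for 3 and in P1 for 1 (Fmo2) of 5 (median log2 -2.24), with Cygb at 335 against 1.26 CPM. Complement genes passed it for all 7 measured (median log2 -5.02, or -5.77 with 0-count genes at their bounds without added CPM), with C3 at 3132 against 2.52 CPM. Chemokines and cytokines passed it in P2 for 7 of 10 (median log2 -2.80, or -3.96 with 0-count genes at their bounds without added CPM), with Il33 at 206 against 1.42 CPM and Ccl11 at 488 CPM against 0 counts (at least 1031-fold). Dissociation response genes passed it for 10 of 14 (median log2 -3.02), with Fos at 5840.3 against 27.5 and Fosb at 1892 against 6.47 CPM. Adventitial fibroblast genes passed it for 7 of 8 (median log2 -6.78, or -7.34 with 0-count genes at their bounds without added CPM) and ductal or myofibroblast genes for 3 of 4 (median log2 -2.96). Hox genes passed it in P2 for 4 and in P1 for 2 of 9 (median log2 -1.61, or -5.44 with 0-count genes at their bounds without added CPM), with Hoxc8 at 65.8 CPM against 0 counts (at least 139-fold) and Hoxa5 at 8.55 against 178 CPM in P2 against P1. Angiogenic ligands passed it in P2 for 7 (Angptl2, 297 against 6.15 CPM) and in P1 for 4 (Pdgfb, 319 against 0.282 CPM) of 19, with a median log2 of -0.58 against random lists at -0.15 to 0.70. The 4 measured lung mesenchyme transcription factors had a median log2 of 1.965, with 2 past 4-fold in P1, Foxf1 at 714 against 0.282 and Tbx2 at 318 against 9.32 CPM. With the P1 libraries exchanged, that median was -0.49, and the log2 ratios of Hpgd and Sftpc were -1.12 and -0.022. The mural list had a median of 1.28, above its random range of -1.37 to 1.25, with 0 of 4 members past 4-fold. Medians inside the random range were those of the fatty acid handling (0.66), committed preadipocyte (0.09), lung alveolar fibroblast (-0.84), and mesenchymal stromal surface marker (0.43) lists. So were those of the endothelial to mesenchymal transition (-0.61), interferon response (0.08), erythroid (1.56) and sort gate (2.0004) lists. The proliferation, T or NK, B, neutrophil, muscle and adipocyte lists had no member at 20 CPM, and the mesothelial, macrophage, platelet and Schwann lists had too few for a median.

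The same comparison in lung set the library labelled lung P1 against lung P2. The library labelled lung P1 carried endothelial genes and genes of fatty acid handling, and lung P2 those of alveolar fibroblasts. Fabp4 stood at 12392 CPM (12186 to 12601) against 16.8 CPM (12.9 to 21.4), and Rbp7, a retinoid binding protein gene, at 759.9 CPM against 0 counts, at least 967-fold higher. Ccl21a, a chemokine of lymphatic vessels, stood at 970.6 CPM against 0 counts (at least 1235-fold), and Plvap, Ly6c1, Gpihbp1 and Emcn at 2875 against 42.9, 2285 against 47.7, 1267 against 28.3 and 749 against 17.3 CPM. Cd300lg (589.7 CPM (545 to 637) against 0.262 CPM (0.00663 to 1.46)), Lrg1 and Fam167b completed the 10 highest ratios. Inmt, a methyltransferase gene of alveolar fibroblasts, stood at 4931 CPM (4861 to 5002) against 7.2 CPM (3.11 to 14.2) in P2 against P1, and Npnt and Ogn at 3082 against 13.5 and 2231 against 12.6 CPM. Mfap4 at 2080.1 CPM (2035 to 2126) against 1.8 CPM (0.218 to 6.5) and Itga8 at 1107 CPM (1074 to 1141) against 1.8 CPM (0.218 to 6.5) rested on 2 counts each in P1. Sftpc stood at 3872 CPM against 0 counts (at least 1434-fold) and Aldh1a1, of retinoic acid synthesis, at 814 CPM against 0 counts (at least 301-fold), and Pcolce2, Pdgfra and Plxdc2 completed the 10 lowest. Of 4791 genes, 402 were at least 4-fold higher in P1 and 562 in P2; TMM scaling shifted the median of all genes by 0.09 log2 and median-of-ratios scaling by 0.18, with 43.7% and 45.9% of calls in P1 in place of 41.7%.

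All 12 endothelial markers passed 4-fold in the library labelled lung P1 (median log2 3.91, random lists -1.15 to 1.78). So did 7 of 8 capillary genes (median log2 4.54). It was passed by 4 of 8 arterial genes (median log2 2.60; Sox17 at 249 against 6.81 and Gja4 at 192 against 9.43 CPM). It was also passed by 4 of 8 venous genes (median log2 1.94; Lrg1 at 801 against 9.69 CPM). The venous factor Nr2f2 was on the P2 side at 87.3 against 867 CPM. Fatty acid handling genes passed it for 7 of 11 (median log2 3.38), including the transcription factor Tcf15 (149 against 1.05 CPM). The lung aerocyte list split and lay inside its random range, with 1 gene past 4-fold in P1 and 3 in P2 of 7 (median log2 0.25): Tbx2, Emp2 and Fibin stood at 11.7 against 692, 45.9 against 613 and 4.5 against 102 CPM. Hpgd, of the general capillary list, stood at 2.7 CPM (0.557 to 7.89) against 144 CPM (132 to 156). Within lung P2, Hpgd stood at 2335 CPM in the endothelial-like cluster of 26 cells and at 14.1 CPM in the other cells. The general capillary list had 5 genes past 4-fold in P1 and 3 in P2 of 8 (median log2 2.39). Angiogenic receptors passed it in P1 for 8 and in P2 for 2 of 14 (median log2 2.13), and Notch pathway genes for 5 and 1 of 12 (median log2 1.73; Jag2 at 156 against 4.45 and Heyl at 1.8 CPM (0.218 to 6.5) against 87.2 CPM (78.1 to 97.1)). Lymphatic markers passed it for 4 of 5 (median log2 2.53, or 5.41 with 0-count genes at their bounds without added CPM). Dissociation response genes passed it in P1 for 10 of 14 (median log2 2.31; Hspa1a at 2473 against 166 and Fosb at 926 against 56.3 CPM). Interferon response genes passed it in P1 for 4 of 9 (median log2 1.84; Rsad2 at 136 against 1.05 CPM). Erythroid genes passed it in P1 for all 4 measured (median log2 4.001; Hbb-bs at 3894 against 173 CPM), while with all barcodes the erythroid median was -0.03. With the P1 libraries exchanged, directions in lung turned for the dissociation response (median -1.41; Fosb -2.01) and the erythroid list (median -0.22; Hbb-bs -0.14). They also turned for Hpgd (4.03), Emp2 (1.71) and Fibin (1.9999). Chemokines and cytokines had 3 in P1 (Cxcl12, 1034 against 125 CPM) and 1 in P2 (Cxcl14, 15.3 against 666 CPM) of 7, with a median log2 of 1.85.

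Lung P2 was at least 4-fold higher for 7 of 8 alveolar fibroblast genes (median log2 -5.82, or -6.74 with 0-count genes at their bounds without added CPM). The same held for 10 of 12 fibroblast markers (median log2 -3.58; Col6a3 at 761 against 29.7 CPM in P2 against P1). It held for 13 of 15 interstitial matrix genes, with 1 at least 4-fold higher in P1 (median log2 -2.99; Col6a1 at 889 against 36.9 and Lox at 389.9 against 13.5 CPM). Of 7 lung mesenchyme transcription factors 5 passed 4-fold in P2 (median log2 -3.41, or -5.01 with 0-count genes at their bounds without added CPM), with Tcf21 at 327 and Tbx4 at 284 CPM against 0 counts each (at least 121- and 105-fold). Angiogenic ligands passed it in P2 for 9 and in P1 for 3 of 18 (median log2 -1.76), with the Tie2 ligand Angpt1 at 374 CPM against 0 counts (at least 139-fold), Vegfd at 384 against 5.4 and Fgf7 at 166 CPM (153 to 179) against 1.8 CPM (0.218 to 6.5). Complement genes passed it for 6 of 7 (median log2 -3.49) and mesenchymal stromal surface markers for 4 of 9 (median log2 -1.93; Alcam at 349 against 15.3 CPM). Adventitial fibroblast genes passed it for 5 of 7 (median log2 -2.24). Ductal or myofibroblast genes passed it in P2 for 2 of 4 (median log2 -1.91). Interstitial adipose progenitor genes passed it in P2 for 3 and in P1 for 1 (Anxa3) of 6 (median log2 -1.99, or -2.39 with 0-count genes at their bounds without added CPM). Adipogenesis-regulatory stroma genes passed it in P2 for 5 of 6 (median log2 -2.49), with Mgp, an inhibitor of calcification, at 11538 against 1071 CPM. Epithelial markers had 4 in P2 and 2 in P1 of 7 (median log2 -2.43, or -4.03 with 0-count genes at their bounds without added CPM), the latter with Krt18 at 211 against 11.8 CPM. Their median was -0.93 with endothelial-like P1 cells against fibroblast-like P2 cells, which leaves out the epithelial cluster of lung P2. The sort gate list had a median of 3.02, above its random range of -2.65 to 2.24. Medians inside the random range were those of the committed preadipocyte (0.83), Hox (0.30), basement membrane (0.83), endothelial to mesenchymal transition (-0.35), antigen presentation (0.63), mural (-0.69) and mesothelial (1.22) lists. The proliferation, T or NK, neutrophil, Schwann and muscle lists had no member at 20 CPM, and the macrophage, B, platelet and adipocyte lists had too few for a median.

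The populations were also compared across tissues, over 3904 genes. Among the genes with the largest differences, those higher in P1 in both tissues included endothelial genes, such as Plvap, Gpihbp1, Emcn, Egfl7, Esam, Robo4, Flt1, Sox17, Sox18, Tie1, Kdr and Pdgfb, and others such as Srgn, Scarb1 and Id1. Those higher in P2 in both included genes of fibroblasts and matrix, such as Ogn, Pcolce2, Gsn, Gpc3, Loxl1, Dpep1, Col6a3, Col6a1, Mmp2 and Col1a2, and others such as Lrp1, Celf2 and Vgll3. The shared genes were not tested for enrichment. At least 4-fold differences were shared by 158 genes higher in P1 (30.9 if the tissues were independent) and 163 genes higher in P2 (26.0 if independent). Opposite differences were found for 40 genes higher in P1 as labelled in fat and in P2 in lung, among them Sftpc, Tbx2, Hpgd, Emp2 and Foxf1. The converse was found for 26 genes higher in P2 in fat and in P1 as labelled in lung, among them Socs3, Fosb, Atf3, Junb and Ptn. Within lung P2, Hpgd stood at 2335 CPM in the endothelial-like cluster of 26 cells and at 14.1 CPM in the other cells. Across genes, which are not independent replicates, Pearson's r was 0.34 and Spearman's rho 0.15. With the P1 libraries exchanged between the tissues, an alternative chosen after the counts were seen, r was 0.68 and rho 0.58 over 3516 genes, 199 and 174 genes were shared, and 13 and 7 were opposite.

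**Figure D2:**
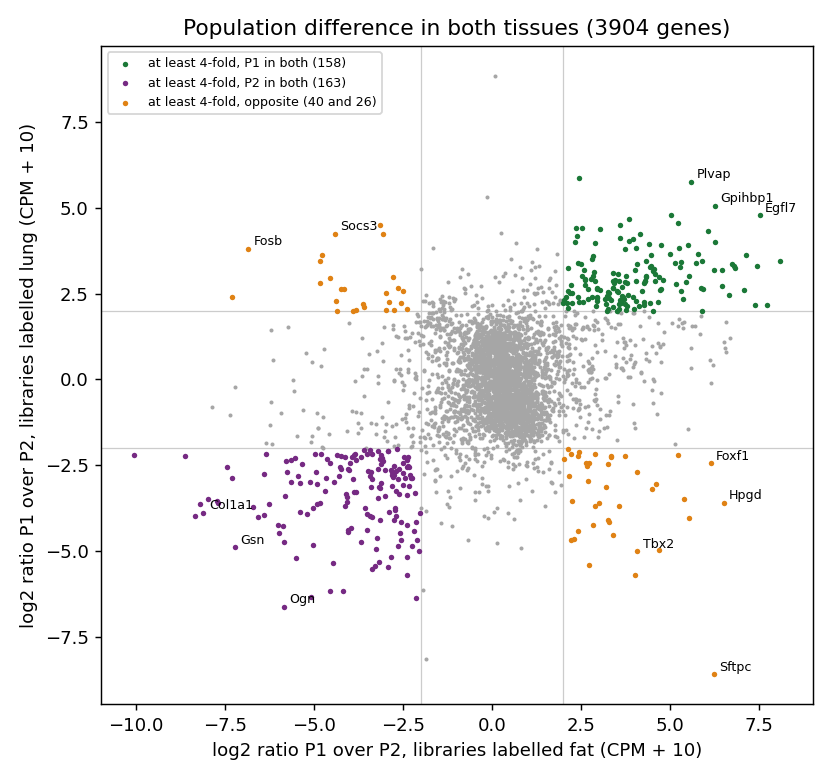
Log2 ratio of P1 over P2 (CPM plus 10) in the libraries labelled fat (horizontal axis) and labelled lung (vertical axis) for the 3904 genes with at least 50 CPM in a library of each tissue. Each point is a gene and grey lines mark 4-fold. Coloured points are the 158 genes higher in P1 in both tissues, the 163 higher in P2 in both, and the 40 and 26 with opposite differences.

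The tissue comparison of P1 asked how endothelial-like cells labelled lung differed from those labelled fat, with directions as labelled. Barcodes of endothelial-like clusters labelled lung P1 held RNA of fatty acid handling, immediate early and matrix genes. Endothelial-like cells labelled fat P1 carried the genes of lung capillaries. The barcodes labelled lung P1 were not shown to be single cells, so their matrix RNA cannot be assigned to endothelial cells. Fabp4 stood at 12142 CPM (11917 to 12371) against 19.3 CPM (15.7 to 23.4), Rbp7 at 739.6 against 2.12 CPM, and Ccl21a at 1017 CPM against 0 counts (at least 1759.7-fold). The immediate early genes Fos, Fosb, Junb and Egr1 stood at 3636 against 12.1, 852 against 1.93, 2849 against 47.4 and 1253 against 17 CPM, and Hspg2, S100a6 and Gsn completed the 10 highest ratios. On the other side, Hpgd, of prostaglandin breakdown, stood at 2728 CPM (2683 to 2773) against 3.29 CPM (0.679 to 9.62) in cells labelled fat P1 against cells labelled lung P1, and Tmem100, Emp2, Scn7a and Fibin at 1845 against 29.6, 2218 against 51.6, 1603 against 6.58 and 533 against 5.49 CPM. Foxf1 (756 CPM (732 to 779.6) against 3.29 CPM (0.679 to 9.62)), Sema3c and Hpgd rested on 3 counts each in the library labelled lung P1, and Sftpc, Nckap5 and Adrb1 had 0 counts there (at least 272-, 161- and 102-fold). Unnamed and epithelial clusters were left out on the side labelled fat P1, among them those led by Ccl21a, by Igkc and Fabp4, and by Ager and Gsn. Over all kept cells the values labelled lung against labelled fat were 12392 against 96.6 CPM for Fabp4, 970.6 against 36.9 for Ccl21a and 570.8 against 134 for Gsn, and the median log2 of lymphatic endothelial genes was 1.85. Of 4627 genes, 281 were at least 4-fold higher in cells labelled lung P1 and 302 in cells labelled fat P1. TMM and median-of-ratios scaling shifted the median of all genes by 0.15 and 0.19 log2. The counts became 307 and 272 with TMM and 317 and 261 with median-of-ratios scaling, so that the larger side changed.

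All 9 lung aerocyte genes were at least 4-fold higher in cells labelled fat P1 (median log2 -3.74, random lists -1.30 to 1.15). Prx was among them (labelled lung at 2.19 CPM (0.266 to 7.93) against 388 CPM (371 to 405) labelled fat). Higher there too were 5 of 8 general capillary genes (median log2 -2.07) and 2 of 3 lung mesenchyme transcription factors (median log2 -4.06). Cells labelled lung P1 were at least 4-fold higher for 6 of 10 fatty acid handling genes (median log2 3.09; Fabp5 at 536 against 10.4 CPM). The same held for 11 of 14 dissociation response genes (median log2 3.77). It held for 4 of 8 Hox genes (median log2 1.56; Hoxd8 at 59.3 CPM against 0 counts, at least 103-fold), with Hoxa5 on the other side at 23 against 176 CPM. The barcodes labelled lung P1 also held more fibroblast RNA. Past 4-fold were 9 of 11 fibroblast markers (median log2 2.94, or 3.12 with 0-count genes at their bounds without added CPM) and 11 of 13 interstitial matrix genes (median log2 2.49). Past it too were 5 of 11 basement membrane genes (median log2 1.85) and all 4 measured adventitial fibroblast genes (median log2 2.75), with Dcn at 316 against 2.89 CPM. Erythroid genes passed it for all 4 measured (median log2 4.39; Hbb-bs at 4156 against 163 CPM). Mural genes passed it in cells labelled lung P1 for 4 of 6 (median log2 2.29). Complement genes passed it in cells labelled lung P1 for 3 of 5 (median log2 2.60, or 3.45 with 0-count genes at their bounds without added CPM). Chemokines and cytokines passed it in cells labelled lung P1 for 2 of 5 (median log2 1.95, or 5.63 with 0-count genes at their bounds without added CPM). Lymphatic markers passed it in cells labelled lung P1 for 3 and in cells labelled fat P1 for 1 (Lyve1) of 5 (median log2 2.31, or 3.54 with 0-count genes at their bounds without added CPM). Venous genes passed it in cells labelled lung P1 for 4 and in cells labelled fat P1 for 1 of 8 (median log2 1.35). In the same order, capillary genes passed it for 4 and 1 of 8 (median log2 1.82). Genes of endothelial to mesenchymal transition passed it for 5 and 2 of 9 (median log2 2.49). Because the barcodes labelled lung P1 also held fibroblast RNA, these values are no evidence of a transition in endothelial cells. The mesenchymal stromal surface markers had a median of -1.16, below their random range, with 0 members past 4-fold. Inside the random range lay the arterial (-0.17), interstitial adipose progenitor (-0.89), committed preadipocyte (0.25) and adipogenesis-regulatory stroma (1.68) lists. So did the angiogenic ligand (-0.08), angiogenic receptor (-0.62), Notch pathway (0.27), interferon response (0.16), antigen presentation (-1.06), endothelial (-0.22), epithelial (0.33, or -0.26 with 0-count genes at their bounds without added CPM) and sort gate (-0.60) lists. The proliferation, T or NK, neutrophil, Schwann and muscle lists had no member at 20 CPM. The alveolar fibroblast, ductal or myofibroblast, mesothelial, macrophage, B, platelet and adipocyte lists had too few for a median.

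Small endothelial-led clusters in the P2 libraries, whose labels their fibroblasts did not contradict, gave a second view of the tissues. The cluster of fat P2 (17 cells, 112876 UMIs) and that of lung P2 (26 cells, 212890 UMIs) carried Fabp4 at 9727 and 254 CPM, Rbp7 at 159 CPM and 0 counts, Hpgd at 8.86 and 2335 CPM, Foxf1 at 8.86 and 409 CPM and Emp2 at 133 and 1376 CPM. Each gene thus ran in the opposite direction to the P1 libraries as labelled. The fat P2 cluster held all 12 fibroblast and all 12 endothelial markers at 100 CPM or more, with a median of 2402 UMIs per cell. The lung P2 cluster held 12 endothelial and 3 fibroblast markers at that level, with a median of 4435.5 UMIs. Fibroblast RNA in the fat P2 cluster was not separated from its endothelial RNA.

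**Figure D3:**
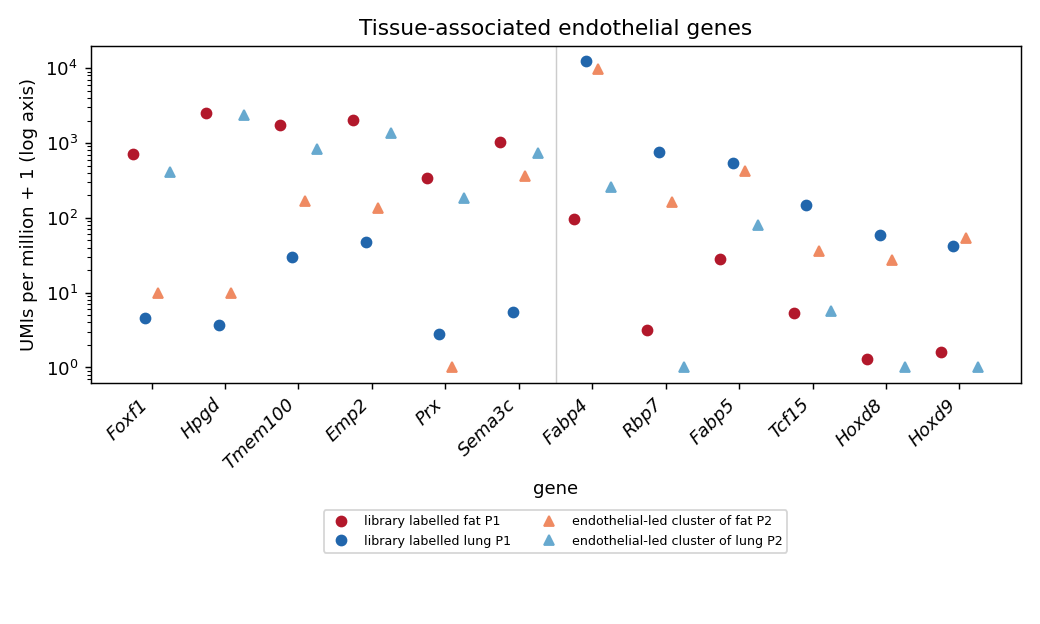
CPM plus 1 (log axis) of 12 genes chosen after the counts were seen, in the libraries labelled fat P1 and lung P1 (circles, all kept cells) and in the endothelial-led clusters of fat P2 and lung P2 (triangles, 17 and 26 cells); each point is 1 library or cluster. Foxf1 is at 714 CPM in the library labelled fat P1 and at 409 CPM in the lung P2 cluster, and Fabp4 is at 12392 CPM in the library labelled lung P1 and at 9727 CPM in the fat P2 cluster.

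The tissue comparison of P2 asked how fibroblast-like cells of lung differed from those of fat. Lung P2 cells carried the genes of alveolar fibroblasts and fat P2 cells those of interstitial adipose progenitors. Npnt, a matrix gene of alveolar fibroblasts, stood at 2879 CPM (2809.8 to 2950.2) against 0.347 CPM (0.185 to 0.594), and Itga8, Mgp and Lrat, of retinoid storage, at 1066 against 8.55, 15404 against 285 and 495 against 0.748 CPM. Mylk, Nebl, Lbh, Scn3a, Cdo1 and Sftpc completed the 10 highest ratios, for example Nebl at 634 against 0.187 CPM. Sftpc stood at 821 CPM in these lung cells and at 93499 CPM in the lung P2 epithelial cluster of 21 cells. The source of its RNA in the fibroblast-like cells was not tested. In fat against lung, Smpd3 stood at 914 CPM (904 to 923) against 3.98 CPM (1.82 to 7.55), and Anxa3, Dpp4, Sfrp2 and Postn at 1297 against 17.2, 576 against 6.63, 507 against 3.98 and 984 against 19 CPM. Sbsn, Ly6c1, Prss23, Efhd1 (278 CPM (273 to 284) against 0.442 CPM (0.0112 to 2.46)) and Akr1c18 (276 CPM against 0 counts, at least 208-fold) completed the 10 lowest. Ly6a stood at 1979 CPM (1965 to 1993) against 156 CPM (140.2 to 173) and Tek at 168 CPM (164 to 172) against 13.7 CPM (9.31 to 19.5) in fat against lung. Of 4256 genes, 321 were at least 4-fold higher in lung and 194 in fat. TMM scaling shifted the median of all genes by -0.51 log2 and the counts became 227 and 310, so that lung held 42.3% of the calls in place of 62.3%.

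All 8 alveolar fibroblast genes (median log2 4.67, random lists -1.34 to 0.89) and 4 of 7 lung mesenchyme transcription factors (median log2 2.47; Tbx2 at 669 against 9.35 and Tbx4 at 284 against 0.134 CPM) were at least 4-fold higher in lung. Interstitial adipose progenitor genes passed 4-fold in fat for 8 of 10 (median log2 -3.60; Creb5 at 521 against 19.5 CPM in fat against lung). Adventitial fibroblast genes passed it in fat for 5 of 8 (median log2 -2.58; Pi16 at 4363 against 340.5 CPM). Chemokines and cytokines passed it in fat for 7 of 10, with 1 in lung (median log2 -2.32; Ccl11 at 498 against 34.5 and Cxcl1 at 171 against 1.77 CPM). Dissociation response genes passed it in fat for 5 of 14 (median log2 -1.63; Fosb at 1886 against 76.9 CPM). Interferon response genes passed it in fat for 1 of 8 (median log2 -1.48; Isg15 at 72.2 against 5.31 CPM), and Hox genes in fat for 4 and in lung for 2 of 10 (median log2 -0.49), with Hoxc8 at 67.1 CPM in fat against 0 counts in lung (at least 50.6-fold) and Hoxa5 at 8.73 against 155 CPM. Angiogenic ligands passed it in lung for 2 and in fat for 1 of 17 (median log2 1.15), with Angpt1 at 331 against 22.1 and Angptl4 at 149.9 against 29.8 CPM in lung against fat. Mural genes passed it in lung for 4 of 6 (median log2 2.26; Tagln at 154 against 3.45 CPM). Stromal surface markers passed it in lung for 3 of 8 (median log2 0.89; Alcam at 332 against 11.3 CPM). Aerocyte genes passed it in lung for 2 of 5 (median log2 1.24). Antigen presentation genes passed it in lung for 1 of 7 (median log2 1.38). Erythroid and epithelial markers passed it in lung for 2 and 3 of 3 each (median log2 2.18, and 2.17, or 6.35 with 0-count genes at their bounds without added CPM). The sort gate list had a median of -1.48, below its random range of -1.35 to 1.35. Inside the random range lay the venous (0.53), fatty acid handling (-0.62), committed preadipocyte (-0.95), adipogenesis-regulatory stroma (0.80), and ductal or myofibroblast (-0.82) lists. So did the angiogenic receptor (-0.32), Notch pathway (0.75), interstitial matrix (-1.003), basement membrane (-0.61), endothelial to mesenchymal transition (0.62), complement (-0.50) and fibroblast (-1.01) lists. The proliferation, lymphatic, T or NK, neutrophil, muscle and adipocyte lists had no member at 20 CPM. The arterial, capillary, general capillary, endothelial, mesothelial, macrophage, B, platelet and Schwann lists had too few for a median.

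**Figure D4:**
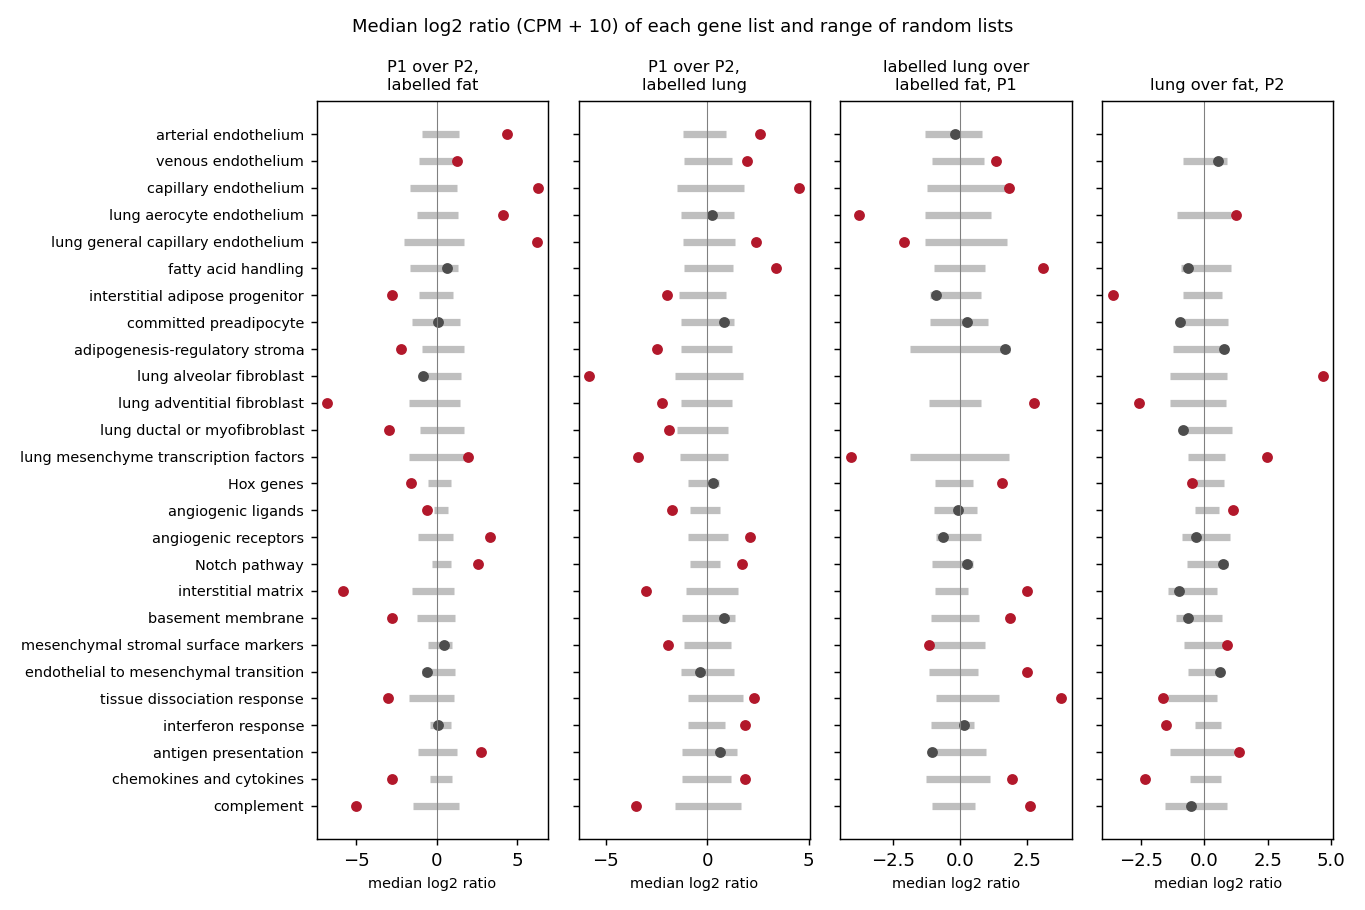
Median log2 ratio (CPM plus 10) of each gene list in the 4 comparisons, with P1 libraries as labelled; points are medians over measured members and grey bars hold 95% of the medians of 10000 random lists matched on expression, red points lying outside the bar. Lung aerocyte genes have a median of 4.08 for P1 over P2 in fat and of -3.74 for labelled lung over labelled fat in P1.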

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

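Every test in this part was chosen after the results had been seen. Differences of the population effect between fat and lung drew attention because they ran in opposite directions in the tissues; with 1 library per group these differences were not tested. They comprised 40 genes at least 4-fold higher in P1 as labelled in fat and in P2 in lung, and 26 genes the other way round. Median log2 ratios P1 over P2 in fat and lung were 1.965 and -3.41 for lung mesenchyme transcription factors (such as Foxf1 and Tbx2), -3.02 and 2.31 for the dissociation response (Fosb, Atf3 and Junb), -2.80 and 1.85 for chemokines and cytokines, and 1.84 and -2.43 for epithelial markers (Sftpc and Ager). With endothelial-like P1 cells against fibroblast-like P2 cells, without the epithelial and other clusters, the epithelial medians were 1.24 and -0.93. In fat, random lists for all kept cells ranged from -1.48 to 1.26. The other lists named here kept opposite medians in that setting.

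Part of the opposite directions may come from an exchange of the tissue labels of the P1 libraries. Across 496 genes at least 4-fold higher in an endothelial-led cluster of a P2 library than in its other cells, the ratio of the libraries labelled fat P1 and lung P1 had r -0.77 (rho -0.72) with the ratio of the endothelial-led clusters of fat P2 and lung P2, which an exchange predicts. Lung RNA mixed into fat endothelial cells would leave the genes of the fat cluster, such as Fabp4, near their level, but the 20 of these genes highest in the fat over the lung cluster stood at a median of 0.0231 of it (quartiles 0.00528 and 0.0567) in the library labelled fat P1 and at 1.15 in the one labelled lung P1. Fat endothelial cells that use lung genes in the tissue itself would carry them in the fat P2 cluster too, but 20 such genes had a median log2 ratio of -3.86 for fat over lung there, with 19 higher in lung. With the exchange, the medians in fat and lung were -0.49 and -1.72 for lung mesenchyme transcription factors and -0.18 and -1.41 for the dissociation response, no longer opposite. They were -2.34 and 0.0146 for chemokines and cytokines and 0.30 and -0.16 for epithelial markers. With an exchange these lists did not come to share a direction, but the lung chemokine median and both epithelial medians became small. No random range was drawn for the exchanged libraries. The clusters hold 17 and 26 cells, and that of fat P2 carried all 12 fibroblast markers beside all 12 endothelial ones. Genotypes of the animals were not analysed here, and an exchange remains a hypothesis that only the submitters' records can settle.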

How the results depend on the processing

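Exchanging the P1 libraries between the tissues and naming clusters by markers alone were chosen after the results had been seen, and all other settings before. Across settings 2310 values of genes stayed within their counting error, 1777 moved and 25 turned direction. Of list medians, 389 stayed within a fixed log2 tolerance that is not a counting error, 615 moved further and 4 turned direction. Of counts of genes 70 stayed within 1.5 times the first count, which leaves room for a changed balance of the directions, and 10 moved further. Of the other values, measures of agreement between tissues stayed 24 times (correlations within counting error, counts within 1.5 times) and moved 12 times, sort gate shares 17 and 31 times, and all 32 shares of cell classes moved. Turned is said here only of genes at least 4-fold apart and of lists outside their random range. None of these turned under another scaling or pseudocount, while smaller ratios could change sign, such as Ly6a in fat from 0.31 to -0.18 with TMM scaling and -0.15 with the P1 libraries exchanged. Each value below was obtained under 1 setting at a time, and the cause of a move was not tested. With 1 library per group no library could be left out, and both kinds of interval cover counting error only. No paired analysis was possible because the labels name no animal shared between libraries.

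With the P1 libraries exchanged, the log2 ratios P1 over P2 that turned direction in fat were Hpgd -1.12, Hspg2 1.16, Junb 0.59 and Sftpc -0.022, and the median of lung mesenchyme transcription factors was -0.49. In lung they were Ackr1 -0.0511, Ager 1.18, Atf3 -0.46, Cxcl1 -0.14, Emp2 1.71, Fibin 1.9999, Fosb -2.01, Hba-a1 -0.21, Hba-a2 -0.51, Hbb-bs -0.14, Hbb-bt -0.22, Hoxa5 0.16, Hpgd 4.03, Hspg2 -2.64, Pparg -0.36, Selp -0.0552 and Sema3c 3.62. In lung the medians of the dissociation response and erythroid lists were -1.41 and -0.22. With all barcodes, the ratios that turned in lung were Hba-a1 -0.0148, Hba-a2 -0.0536 and Hbb-bt -0.89, and the erythroid median was -0.0342. With all kept cells in the P2 tissue comparison, Slco2a1 turned to 0.21.

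With a 2-fold threshold in place of 4-fold the counts of genes were 1228 for P1 and 809 for P2 in fat, 1111 and 1327 in lung. They were 642 labelled lung and 1284 labelled fat in P1, and 769 in lung and 588 in fat in P2. The fat side of the P2 tissue comparison held 310 genes with TMM and 306 with median-of-ratios scaling. Pearson's r and Spearman's rho of the population difference between tissues were 0.38 and 0.15 with a pseudocount of 1 CPM, 0.33 and 0.10 with means over cells, 0.45 and 0.20 with endothelial-like against fibroblast-like cells and 0.30 and 0.13 with a minimum of 10 CPM. With the P1 libraries exchanged they were 0.68 and 0.58, with 13 and 7 genes in opposite directions.

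The shares of endothelial-like cells in the libraries labelled fat P1 and lung P1 and of fibroblast-like cells in fat P2 and lung P2 are given in the order labelled fat P1, fat P2, labelled lung P1, lung P2. They were 38.6%, 95.8%, 0% and 91.8% at resolution 0.5 and 78.2%, 90.1%, 88.3% and 73.8% at resolution 2. They were 66.8%, 79.1%, 89.2% and 65.8% with 1000 variable genes and 83.7%, 91.2%, 88.0% and 63.8% with 15 principal components. They were 74.3%, 98.0%, 62.0% and 76.5% with at most 5% mitochondrial UMIs and 50.5%, 92.9%, 91.1% and 80.2% without doublet removal. They were 56.6%, 73.0%, 100% and 72.0% with Scrublet's automatic threshold and 98.0%, 100%, 100% and 91.6% with clusters named by markers alone.

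Thinned to 1000 UMIs, the shares of cells with a sort gate gene that moved were Tek 46.5%, Pecam1 79.4%, Eng 68.0% and Ly6a 75.4% in the library labelled fat P1 and Tek 14.9%, Pdgfra 33.6%, Eng 4.18% and Ly6a 71.5% in fat P2. They were Ptprc 1.39%, Tek 20.5%, Pecam1 70.7%, Eng 63.5% and Ly6a 80.9% in the library labelled lung P1 and Tek 1.41%, Pdgfra 72.1%, Pecam1 1.55%, Eng 6.06% and Ly6a 4.65% in lung P2. Without thinning they were Tek 71.6%, Pecam1 95.9% and Eng 91.6% in the library labelled fat P1 and Ptprc 0.378%, Tek 47.8%, Pdgfra 76.3%, Pecam1 0.568%, Eng 18.2% and Ly6a 87.8% in fat P2. They were Pecam1 84.7%, Eng 80.0% and Ly6a 91.8% in the library labelled lung P1 and Pdgfra 84.5% in lung P2.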

Other observations

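Every test in this part was chosen after the results had been seen. Hox genes, which mark position along the body axis, differed between the P2 libraries. Hoxc6, Hoxc8, Hoxc9 and Hoxc10 stood at 47.4, 65.8, 42.3 and 33.2 CPM in fat P2, and lung P2 held 2, 0, 0 and 0 counts of them. Hoxa5 and Hoxb5 stood at 159 and 64.7 CPM in lung P2 and at 8.55 and 4.17 CPM in fat P2. In the P1 libraries, Hoxa5 stood at 178 CPM in the one labelled fat and 26.1 CPM in the one labelled lung, and Hoxd8 at 0.316 and 57.6 CPM. Hoxc6, Hoxc8, Hoxc9 and Hoxc10 were near absent from both, with 0 counts each in the library labelled fat P1. The library labelled lung P1 held 4, 0, 1 and 1 counts of them. These genes were chosen after their values were seen. At 2000 UMIs per cell, a proliferation gene was seen in 0.819% (0.424 to 1.43) of 1465 cells labelled fat P1 and 1.07% (0.839 to 1.35) of 6719 fat P2 cells. It was seen in 4.35% (1.77 to 8.75) of barcodes labelled lung P1, which were 7 of 161, and in 1.57% (0.814 to 2.73) of 764 lung P2 cells. At least 3 UMIs of endothelial and 3 of fibroblast markers were seen together in 0.205%, 4.63%, 39.8% and 0.654% of cells in the same order.

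The barcodes of the library labelled lung P1 were alike, which could mean that most of them held free RNA of a single pool. Over 100 genes, the median variance between barcodes was 1.06 times the binomial expectation, against 1.495, 1.41 and 1.74 in the libraries labelled fat P1, fat P2 and lung P2, and 92 of the genes were under 1.2. Within the largest named cluster of each, which leaves out the spread between types of cell, it was 1.24, 1.23 and 1.47 there and 1.02 in the library labelled lung P1. A single uniform type of cell at low depth would keep Xist and Y genes apart if the animals were of both sexes. In the other libraries the share with Xist among barcodes with a Y gene was 0.108 (0.0684 to 0.160, labelled fat P1), 0.306 (0.263 to 0.352, fat P2) and 0.131 (0.0744 to 0.209, lung P2) times that among all barcodes. Among all 649 barcodes, the share with Xist among 22 barcodes with a Y gene was 1.24 (0.668 to 1.86) times that among all. At 2000 UMIs per barcode, 1 of 9 barcodes with a Y gene had Xist, and the ratio was 0.284 (0.00718 to 1.23) over 161 barcodes. A verdict required both intervals to lie on the same side of a bound of 0.5. The interval over all barcodes lay above 0.5, and that at 2000 UMIs spanned it. Free RNA and a single uniform type of cell therefore cannot be told apart on these few barcodes. The sex test followed an earlier one, the dispersion within the largest cluster labelled fat P1, which decided nothing and was replaced once seen. No biological explanation was tested.

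Ly6a and Tek RNA were lower in lung P2 than in fat P2. Low depth of lung P2 is unlikely as the whole cause for Ly6a, since at 1000 UMIs per cell the share of fibroblast-like cells with Ly6a was 13.0-fold higher in fat P2 (73.0%) than in lung P2 (5.61%). For Tek, the shares of all kept cells at 1000 UMIs were 14.9% in fat P2 and 1.41% in lung P2. Low depth is thus unlikely as the whole cause for Tek too. Of the Tek UMIs of lung P2, 72.2% (64.5 to 79.0) lay in its endothelial-led cluster of 26 cells. This share was first set as a test of endothelial cells carried along in the sort, but such cells would add Tek RNA, so it explains no low level and the test is void. A difference of the tissues in Ly6a and Tek use by PDGFRa-positive cells stays open as untested.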
